A study of Homo sapiens with 6 samples.

How the data were processed

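The 6 arrays measured total RNA of IMR90 human lung fibroblasts, 3 untreated and 3 treated with 10 ng/mL recombinant human oncostatin M, and groups and replicate numbers were taken from the labels. RNA was purified on RNeasy columns, and biotin-labelled targets were made with an Ambion kit for whole transcripts, per the labels' protocols. The deposited values are on the log2 scale, 1 per probe set and array, and were made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes, which name the method and the program without settings. No genome build is given in the sources used here, so no coordinates are printed. Array medians lay between 6.54 and 6.66 and correlations between arrays between 0.9875 and 0.9978, and no columns were identical. RMA as a method corrects background, makes the arrays' distributions alike and summarises probes, and it tends to shrink differences at low intensity, so changes are relative to the other genes on the array.

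The table holds 33297 probe sets. A gene table of the platform gave exactly 1 gene symbol for 19460, several for 1754 and none for 12083, and no symbol needed updating. The 12083 are unnamed here. For each of the 18417 genes the probe set with the highest mean over the 6 arrays was tested, and 769 genes had a choice of probe sets. No filter on dim probe sets was used. A linear model with the group as its only term was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the genes tested), with a threshold of 0.05 on adjusted p. Figures were drawn with matplotlib 3.10.9.

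For 30 gene lists the members past the threshold were counted over all genes and adjusted over the list alone, and each list was tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 30 lists. The text names the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, up to 4 members per list with the largest change among those past it, and 14 genes named in advance, of which 13 were analysed. The remaining gene was not analysed here, and XIST and Y-linked genes were left out. Genes outside this rule are reported in the closing section and were chosen after their values were seen. Of these, BMP5, TMEM108 and NMRAL2P are also named in the Results where levels are set against silent genes. ACTG2, DES, LMOD1 and MYH11 are named there only as members that lists share.

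The model was checked on simulated arrays with the observed means and spreads. With 200 genes changed among 18417, 48.3% of changes of 0.5, 90.4% of changes of 1 and 99.3% of changes of 2 (log2) were recovered, and 3.92% of calls were false. A list of 20 genes shifted by 0.3 was called in 20 of 20 runs, and in 18 with an estimated correlation. In the simulation each gene was drawn independently, with no variation shared between genes and no deviating array. Estimated correlations in the real lists reached 0.698 (cholesterol synthesis and uptake), so these shares need not hold for the real arrays.

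Alternatives covered the normalization between arrays, the choice of probe set, filters on dim genes, the variance prior, array weights, a replicate block, each array left out in turn, stricter thresholds and other list tests. Array weights estimated by limma were 0.226 for oncostatin M 1, 0.723 for control 2 and between 0.867 and 3.225 for the others.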

Results

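IMR90, a line of human lung fibroblasts, was studied with and without recombinant human oncostatin M, a cytokine of the interleukin-6 family that signals through JAK kinases and STAT3. RNA of 3 untreated control samples and of 3 samples given a single dose of 10 ng/mL was hybridised to gene-level Affymetrix arrays, 1 array per sample. The comparison asked which transcripts differed in level after oncostatin M. The length of the treatment is not given in the sources used here. Values below are log2 expression levels as mean ± SD over 3 arrays, and changes are oncostatin M minus control on the log2 scale with their standard error (SE). The number of arrays limits the precision. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

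After oncostatin M, 10 of 24 measured genes of STAT3 signalling and feedback were higher and 1 lower at an adjusted p under 0.05 (limma), and 5 of 19 complement genes and 5 of 31 interferon-stimulated genes were higher and none lower. Of 23 immediate early and ERK feedback genes 6 were lower and 1 higher, and of 21 genes of p53 signalling and cell cycle inhibition 4 were lower and none higher. The largest rise was that of SLCO2A1 (probe set 8090823), a prostaglandin transporter, from 7.38 ± 0.10 to 10.46 ± 0.05 (8.45-fold). SOCS3, the feedback inhibitor of JAK and STAT signalling, rose 4.16-fold, and OSMR, a subunit of the oncostatin M receptor, rose 1.76-fold. The largest fall was that of RGS4 (probe set 7906919), a regulator of G-protein signalling, from 9.97 ± 0.27 to 7.58 ± 0.51 (5.24-fold lower). Its place ahead of TNFSF4 rested on oncostatin M 1, the array that differed most from its group. IL6 fell 1.95-fold, to a level where sizes are uncertain, while VEGFA, an angiogenic growth factor, rose 2.00-fold.

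Of 18417 genes tested with limma, 316 were higher and 314 lower at an adjusted p under 0.05, and 70 and 34 of these changed by at least 2-fold. The smallest change called was 0.31, and the groups did not overlap for any of the 630 genes called. Among all genes, 18% had groups that did not overlap, against 10% by chance. Of the 85 genes named by rule that passed, 36 lost their call without at least 1 array. Without control 1, 156 genes were higher and 105 lower, and without control 2 the counts were 188 and 127. Without control 3, 136 genes were lower, and without oncostatin M 2, 179 were lower. Without oncostatin M 1, the array that differed most from its group, 400 were higher and 332 lower, of which 20 were lower by at least 2-fold.

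The files hold no calls of detection, so levels were set against 409 olfactory receptor and keratin-associated protein genes, expected to be silent in fibroblasts, whose means were 4.87 in control and 4.89 after oncostatin M. Of 105 genes named in the texts that passed, 7 lay at or below the percentile of 95 of these genes in both groups, a bound chosen after seeing the data, and no size is given for them (FABP4, CXCL10, IL13RA2, PLA2G4C, GBP2, BMP5 and TMEM108). Another 15 lay there in 1 group, so their sizes are uncertain: DIO2, KYNU, ACP3, AKR1C1, TMTC2, PTGS2, CD14 and NMRAL2P in control, and B3GALT1, EDN1, SEMA3D, CD274, IL6, TNFAIP3 and RGS5 after oncostatin M. Not all of the 409 genes need be silent, since the control level of C1S (10.57) ranked at 99.8% of them. In controls the bound lay between 6.45 (PLA2G4C) and 6.84 (MASP1), well above their mean. Genes within the range of the 409 may therefore be expressed.

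**Figure D1:**
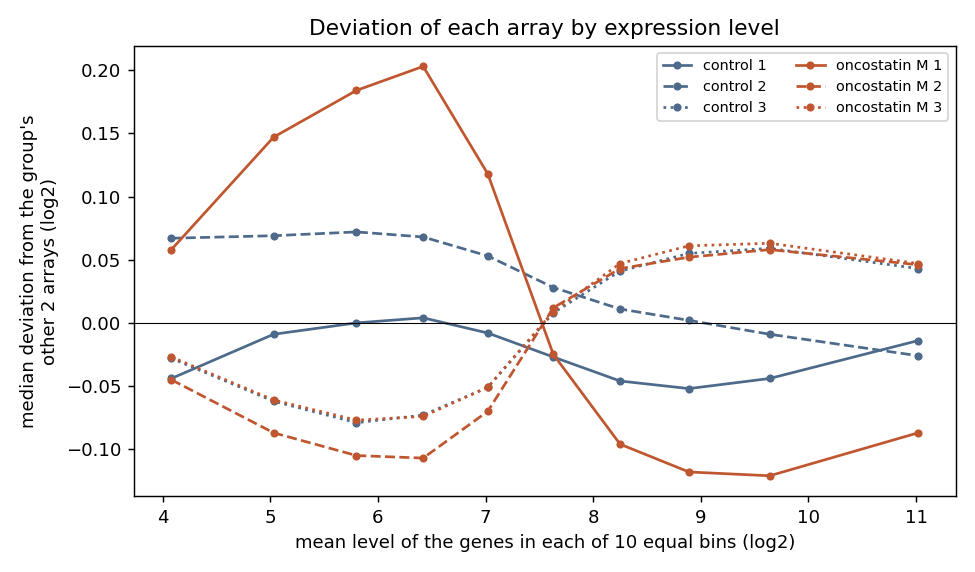
Median deviation of each array from the other 2 arrays of its group (vertical axis, log2) for 10 equal bins of the genes ordered by mean level (horizontal axis, log2), with 1 line per array (blue, control; orange, oncostatin M). Oncostatin M 1 deviates most, by up to 0.20 at a mean level of 6.42 and down to -0.12 at 9.64.

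Besides SLCO2A1 and SOCS3, the 12 largest rises included SHISA3 (change 2.89, SE 0.12), the chemokine CXCL12 (2.76, SE 0.26) and DIO2 (2.60, SE 0.11), which converts thyroxine to the active thyroid hormone. KYNU, an enzyme of tryptophan breakdown, rose by 2.37, and the acid phosphatase ACP3 by 2.15. DEPP1, the actin filament capping protein TMOD1, ARHGAP28 and TMTC2 rose by 1.96, 1.93, 1.81 and 1.69. AKR1C1, an aldo-keto reductase, rose by 1.77 on the probe set used, while its other probe set gave 0.47, and probes of closely related AKR1C genes can cross-hybridise, so its value is uncertain. Adjusted p for these 12 genes ran from 2.29e-06 for SLCO2A1 to 0.00426 for KYNU (limma), and each kept its call when any 1 array was left out.

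Among the 12 largest falls, RGS4 (-2.39, SE 0.24) was followed by TNFSF4 (-2.32, SE 0.12), the ligand of the OX40 receptor on T cells, and B3GALT1 (-2.28, SE 0.19), a galactosyltransferase. RGS4 was lowest on oncostatin M 1 (7.18, against 7.40 and 8.16 in its group). TNFSF4 was lowest on oncostatin M 3 (7.57, against 7.88 and 8.06). The order of RGS4 and TNFSF4 thus rests on oncostatin M 1, the array that differed most from its group. Without that array 20 genes were lower by at least 2-fold, against 34 with it. EDN1, the precursor of endothelin, fell by 1.57, and HBEGF, a ligand of the epidermal growth factor receptor, by 1.52. The semaphorins SEMA3D and SEMA7A fell by 1.46 and 1.43, and LRRC17 by 1.41. The fatty acid binding protein FABP4 also fell, to the mean level of silent genes (4.89), so its place among the 12 is uncertain. CD274, which encodes the immune checkpoint ligand PD-L1, fell by 1.38, the transcription factor MYBL1 by 1.37 and the ubiquitin ligase MARCHF4 by 1.33. Adjusted p ran from 9.3e-05 for TNFSF4 to 0.0316 for FABP4 (limma). The call of FABP4 was lost without control 1 (adjusted p = 0.138), oncostatin M 2 (0.0506) or oncostatin M 3 (0.056), and that of MYBL1 without control 1 (0.0637).

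**Figure D2:**
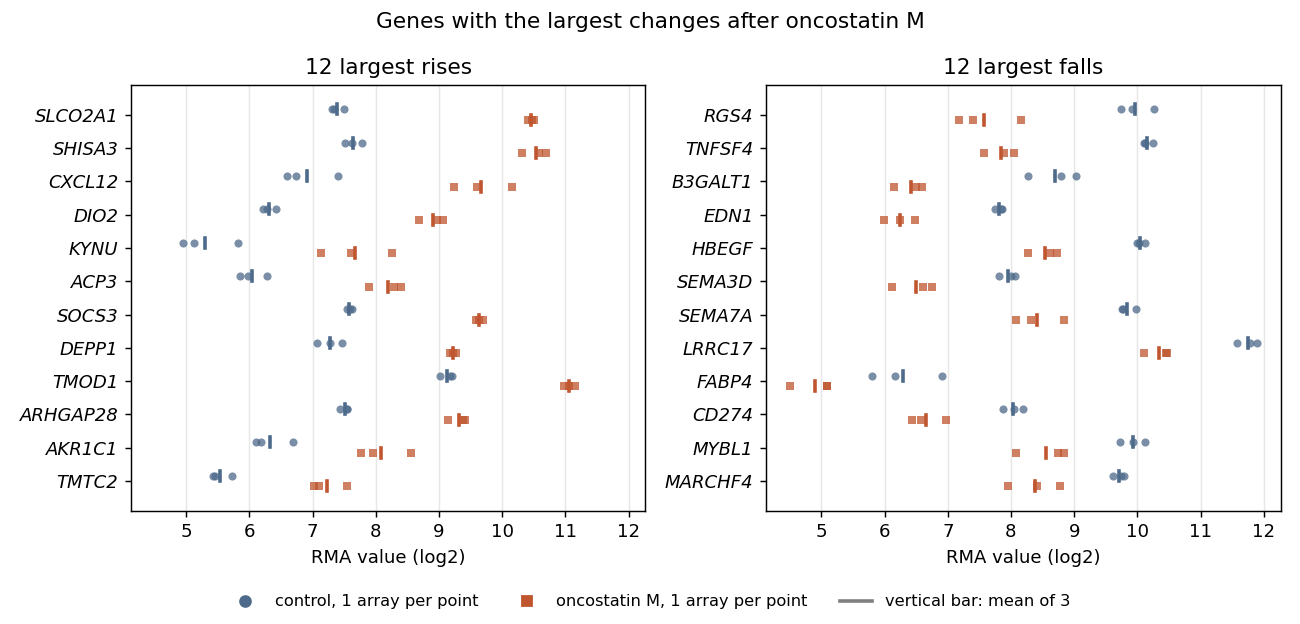
Log2 RMA values of the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per array (circles, control; squares, oncostatin M) and a vertical bar at the mean of 3 arrays. For each of the 24 genes the 3 oncostatin M arrays lie wholly above or wholly below the 3 control arrays, with SLCO2A1 furthest apart (7.38 against 10.46).

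Genes of STAT3 signalling and its feedback were higher on balance. Of 24 measured members, 10 were higher and 1 lower, and when adjusted over the list alone 11 were higher and 4 lower. SOCS3 rose by 2.06 (SE 0.07, adjusted p = 1.25e-05), the kinase PIM1 by 1.34, the transcription factor CEBPD by 1.26 and JUNB by 1.08. STAT3 itself rose by 0.45 (adjusted p = 0.0114). The list stood above other genes with camera at the preset correlation (median 0.16, adjusted p = 3.8e-07 over 30 lists; adjusted p = 0.112 with an estimated correlation). The call of STAT3 was lost without control 1 (adjusted p = 0.0784), control 2 (0.0531) or control 3 (0.0508).

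Receptors and ligands of the interleukin-6 family went both ways. Of 14 measured members, 2 were higher and 2 lower (3 and 4 when adjusted over the list alone), and the list did not stand apart (median -0.017, camera adjusted p = 0.735). OSMR rose by 0.82 (SE 0.07, adjusted p = 0.000641) and IL6R, the interleukin-6 receptor, by 0.51, while IL6 fell by 0.96 (adjusted p = 0.00193) and IL11 by 0.61. The shared signalling subunit IL6ST differed by 0.27 (adjusted p = 0.246), LIFR by -0.073 (0.943) and OSM by 0.071 (0.883), none past the threshold. The call of IL6R was lost without control 1 (adjusted p = 0.063), and that of IL11 in 4 of 6 fits, with adjusted p up to 0.116 without oncostatin M 2.

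Taken as 1 list, immediate early genes and feedback inhibitors of ERK signalling were lower on balance, with 14 members below 0 and 9 above. The classes were not tested apart, and immediate early members went both ways (JUNB and FOSL1 below). Of 23 measured members, 6 were lower and 1 higher, and when adjusted over the list alone 11 were lower and 4 higher. SPRY2 and SPRY4, inhibitors of receptor tyrosine kinase signalling, fell 2.14-fold and 1.59-fold, and the AP-1 subunit FOSL1 fell by 0.59, while JUNB, which also stands in the STAT3 list, was the member that rose over all genes. The list median was -0.14 (camera adjusted p = 0.0102, adjusted p = 0.394 with an estimated correlation). The call of FOSL1 was lost without control 1 (adjusted p = 0.0715), control 2 (0.0785) or control 3 (0.066).

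Complement genes were higher on balance. Of 19 measured members, 5 were higher and none lower, with 6 past the threshold when adjusted over the list alone. MASP1, a protease of the lectin pathway, rose by 1.18 and C1RL by 1.08. C1R and C1S, the proteases of the classical pathway, rose by 0.86 and 0.66, from 10.23 ± 0.20 to 11.09 ± 0.16 for C1R. The median was 0.14 (camera adjusted p = 4.62e-05, adjusted p = 0.213 with an estimated correlation). It was 0.095 without oncostatin M 1 (camera adjusted p = 0.000209) and 0.091 with array weights (camera adjusted p = 0.000611). Of 20 acute phase genes none passed the threshold over all genes or when adjusted over the list alone, although the list as a whole was called higher (median 0.094, camera adjusted p = 0.0338, adjusted p = 0.42 with an estimated correlation). That call was lost without control 2 (adjusted p = 0.0571), control 3 (0.0862) or oncostatin M 1 (0.232), with array weights (0.337) and under 5 other planned processing choices or list tests besides the estimated correlation and the threshold of 0.01. Control means of the 20 acute phase genes ran from 3.28 to 9.90, and most lay below 6.45, within the range of silent genes. The list call and the lack of single calls thus concern mainly genes of low level.

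Chemokines as a list did not stand apart (20 measured, median 0.044, camera adjusted p = 0.385). CXCL12 rose by 2.76 (adjusted p = 0.00115) and CXCL10, an interferon-induced chemokine, fell, with both means within the range of silent genes. CCL2 differed by 0.11 (adjusted p = 0.873), and when adjusted over the list alone 1 member was higher and 1 lower. Other inflammatory mediators were higher on balance, with 5 of 24 higher and 2 lower (11 and 2 when adjusted over the list alone). The interleukin-1 receptor IL1R1 rose by 1.52 and the adhesion molecule VCAM1 by 1.39, the decoy receptor IL13RA2 rose as well, whereas TNFAIP3, an inhibitor of NF-kappaB signalling, fell by 0.99. The median of the list was 0.18 (camera adjusted p = 3.8e-07, adjusted p = 0.132 with an estimated correlation). The call of CXCL10 was lost in 4 of 6 fits (adjusted p up to 0.0752 without control 3), and those of VCAM1 and IL13RA2 without control 1 (0.0554 and 0.0519).

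In the prostaglandin pathway, 2 of 17 genes were higher and 1 was lower (3 and 1 when adjusted over the list alone). PTGS2, the inducible cyclooxygenase, rose by 1.36 (SE 0.08, adjusted p = 0.00018) and the receptor gene PTGER2 by 0.46, while the phospholipase PLA2G4C fell. The median was 0.094 (camera adjusted p = 0.0261, adjusted p = 0.214 with an estimated correlation), and the list call was lost without oncostatin M 1 (adjusted p = 0.082) and with array weights (0.0859). PTGER2 lost its call in 4 of 6 fits and PLA2G4C in 5, both with the highest adjusted p without control 1 (0.152 and 0.195).

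Interferon-stimulated genes were higher on balance: 5 of 31 were higher, none was lower and 7 passed when adjusted over the list alone. IFITM1 rose by 1.27 (SE 0.09), IFI35 by 0.94 and IFI6 by 0.73, and the guanylate-binding protein GBP2 rose as well. The median was 0.11, with 26 of 31 members above 0 (camera adjusted p = 7.41e-07, adjusted p = 0.107 with an estimated correlation). Among 13 genes of class I antigen presentation, the immunoproteasome subunit PSMB9 rose by 0.40, and 3 genes passed when adjusted over the list alone (median 0.089, camera adjusted p = 0.00769, adjusted p = 0.394 with an estimated correlation). That list call was lost without oncostatin M 2 (adjusted p = 0.075), and PSMB9 lost its call in 5 of 6 fits (adjusted p up to 0.0871 without control 1).

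No collagen gene passed the threshold among 20 measured, over all genes or when adjusted over the list alone (median -0.038, camera adjusted p = 0.688). With array weights that list was called lower (median -0.117, adjusted p = 0.0041), and without oncostatin M 1 it was not (-0.088, adjusted p = 0.0836). COL1A1 differed by -0.036 (adjusted p = 0.968). Of 27 other matrix and crosslinking genes, LUM and FBLN2 rose by 0.75 and 0.51 and the lysyl oxidase LOXL1 fell by 0.40, with 5 higher and 5 lower when adjusted over the list alone. The median of that list was -0.076 and its mean 0.012, so these differed in sign, and camera gave an adjusted p of 0.976. Among 26 matrix proteases and inhibitors, 2 were higher and 3 lower, and 2 and 4 when adjusted over the list alone (median -0.096, camera adjusted p = 0.238). ADAMTS1 rose by 1.00 (SE 0.07) and the plasminogen activator PLAT by 0.58, TIMP3 fell by 0.68 and MMP16 by 0.83, with -1.52 on the other probe set of MMP16. TIMP1 differed by 0.17 (adjusted p = 0.386). Calls were lost in 5 of 6 fits for LOXL1 (adjusted p up to 0.0944 without control 2), 4 for MMP16 (0.115 without control 1) and 3 for LUM (0.109 without control 2), and without control 1 for FBLN2 (0.0607) and PLAT (0.0502).

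Contractile and myofibroblast genes were lower on balance. Of 17 measured members, 3 were lower and none higher, 9 passed when adjusted over the list alone, and 15 lay below 0. CNN1, SMTN and TPM1, which encode calponin, smoothelin and a tropomyosin, fell by 0.50, 0.43 and 0.36, and ACTA2 differed by -0.32 (adjusted p = 0.257). The median was -0.18 (camera adjusted p = 4.09e-06, adjusted p = 0.241 with an estimated correlation). Smooth muscle and pericyte markers were lower on balance, with 4 of 14 lower, 5 when adjusted over the list alone and a median of -0.14 (camera adjusted p = 0.000131, adjusted p = 0.112 with an estimated correlation). That list is not independent of the contractile one, since 5 of its 14 members (ACTG2, CNN1, DES, LMOD1 and MYH11) stand in both. Besides CNN1, RGS5 fell by 0.70, CSPG4 by 0.67 and PDGFRB by 0.37. Calls were lost in 6 of 6 fits for TPM1 (adjusted p up to 0.197 without control 1), 5 for PDGFRB (0.127 without control 3), 4 for CNN1 (0.159 without control 1), SMTN (0.14 without control 3) and RGS5 (0.0957 without control 1), and 3 for CSPG4 (0.102 without control 2).

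Of 24 genes responsive to TGF-beta, NOX4, a superoxide-producing oxidase, fell by 0.68, and when adjusted over the list alone 7 were lower and 1 higher (median -0.069, camera adjusted p = 0.0651). With an estimated correlation it did not pass (adjusted p = 0.241), and fry called the list lower (adjusted p = 0.0243). With camera at the preset correlation it passed without control 2 (adjusted p = 0.037) or oncostatin M 2 (0.0261), and NOX4 lost its call without control 1 (0.139), control 2 (0.116) or control 3 (0.0503). Without oncostatin M 1 the list median was -0.031 and the list did not pass (camera adjusted p = 0.175). Among 24 secreted growth factors, 5 were higher and 5 lower (6 and 6 when adjusted over the list alone), and the list did not stand apart (median 0.044, camera adjusted p = 0.434). BMP4 rose by 1.16, VEGFA by 1.00 (SE 0.12, adjusted p = 0.0038) and HGF by 1.00 (SE 0.10), whereas HBEGF fell by 1.52.

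Genes of p53 signalling and cell cycle inhibition were lower on balance, with 4 of 21 lower, none higher and 5 past the threshold when adjusted over the list alone (median -0.20, camera adjusted p = 0.000134, adjusted p = 0.214 with an estimated correlation). ZMAT3 fell by 0.57, the death receptor TNFRSF10B by 0.48, GADD45A by 0.46 and PLK3 by 0.39. CDKN1A, the cyclin-dependent kinase inhibitor p21, differed by -0.20 (adjusted p = 0.448). No gene of the cell cycle list passed among 32 measured, over all genes or when adjusted over the list alone (median 0.025, camera adjusted p = 0.335). Without oncostatin M 1 that list was called higher (median 0.079, adjusted p = 0.000414), as it was with array weights (0.09, adjusted p = 0.00261). Calls were lost in 5 of 6 fits for PLK3 (adjusted p up to 0.127 without control 3), 4 for ZMAT3 (0.161 without control 1) and GADD45A (0.122 without control 2), and 2 for TNFRSF10B (0.0729 without control 2, 0.0685 without control 3).

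All 17 measured genes of cholesterol synthesis and uptake lay below 0, 1 of them past the threshold over all genes and 4 when adjusted over the list alone. STARD4, a carrier of sterols, fell by 0.94 (SE 0.13, adjusted p = 0.00725). The median was -0.19 (camera adjusted p = 9.04e-07, adjusted p = 0.394 with an estimated correlation). It was -0.133 without oncostatin M 1 (camera adjusted p = 0.000937) and -0.123 with array weights (camera adjusted p = 0.00346). Genes of hypoxia and glycolysis were higher on balance, with 3 of 24 higher and none lower, and 7 higher and 2 lower when adjusted over the list alone (median 0.14, camera adjusted p = 0.000671, adjusted p = 0.112 with an estimated correlation). The vasodilator peptide gene ADM rose by 0.91, the carbonic anhydrase CA12 by 0.63 and the hexokinase HK2 by 0.51. CA12 and HK2 lost their calls in 4 of 6 fits each, with the highest adjusted p without control 1 (0.221 and 0.159).

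Of 20 genes of the unfolded protein and amino acid response, the cystine transporter SLC7A11 rose by 0.92 and was the member that passed when adjusted over the list alone (median 0.068, camera adjusted p = 0.078). That list passed without control 1 (adjusted p = 0.0354) or oncostatin M 3 (0.000395) and with a replicate block (0.0231), and SLC7A11 lost its call without control 1 (0.0859) or control 2 (0.052). No gene passed, over all genes or when adjusted over the list alone, among 12 heat shock genes (median -0.068, camera adjusted p = 0.177), 9 metallothioneins (0.078, 0.0938), 19 ribosomal protein genes (0.014, 0.734) and 21 housekeeping genes (0.004, 0.54). The heat shock list passed without control 2 (adjusted p = 0.037) or oncostatin M 3 (0.0403).

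Fibroblast identity markers were higher on balance, with 4 of 20 higher, none lower and 7 past the threshold when adjusted over the list alone (median 0.12, camera adjusted p = 0.000138, adjusted p = 0.241 with an estimated correlation). LUM, which also stands in the matrix list, rose by 0.75, TWIST1 by 0.49, FOXF1 by 0.44 and PDGFRA by 0.39. Besides the smooth muscle and pericyte markers, which were called lower (camera adjusted p = 0.000131, adjusted p = 0.112 with an estimated correlation), 3 lists of markers of other cell types did not pass: camera gave adjusted p = 0.0859 for 18 epithelial, 0.671 for 17 endothelial and 0.173 for 19 leukocyte markers. Single members passed, namely the epithelial MUC1 and KRT18, which rose by 1.12 and 0.52, the leukocyte CD14, which rose by 1.44, and the endothelial FLT1, which fell by 0.53, and 2, 1 and 1 members passed when adjusted over the list alone. The epithelial list passed without control 2 (adjusted p = 0.037), oncostatin M 2 (0.0261) or oncostatin M 3 (0.00414). Calls were lost in 5 of 6 fits for FOXF1 (adjusted p up to 0.0966 without control 1), 4 for TWIST1 (0.0842 without control 1) and PDGFRA (0.157 without control 1), 3 for KRT18 (0.118 without control 1) and 2 for FLT1 (0.0864 without control 1, 0.0631 without control 2).

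**Figure D3:**
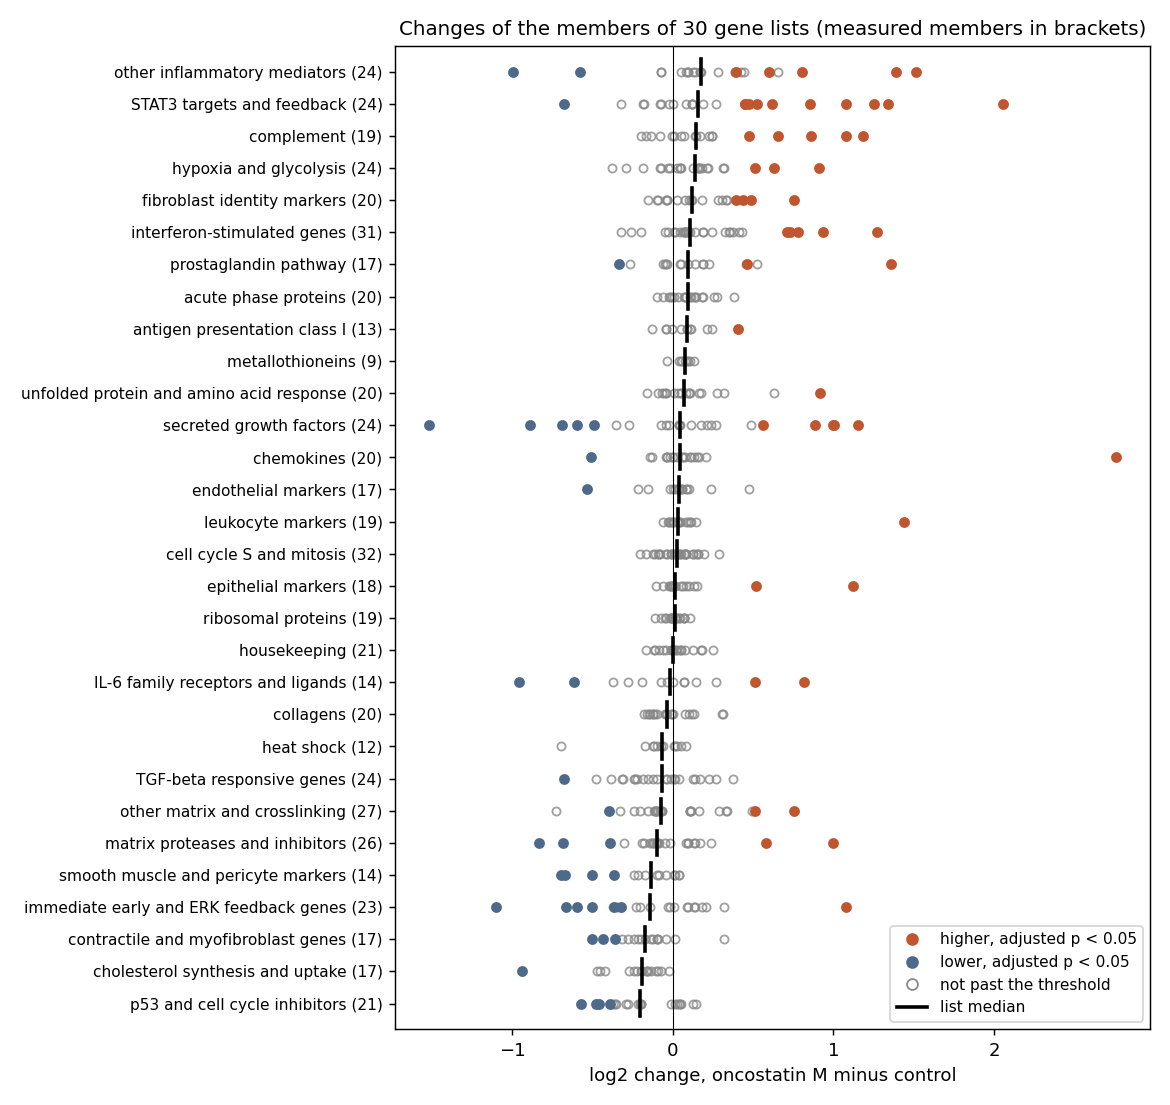
Log2 change, oncostatin M minus control, of every measured member of the 30 gene lists, with the number of measured members in brackets and a black bar at each list's median. Filled points passed an adjusted p of 0.05 over all genes (orange higher, blue lower) and open points did not. Medians run from -0.20 (p53 and cell cycle inhibitors) to 0.18 (other inflammatory mediators).

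In all, 30 lists were tested with camera. At the preset correlation 14 passed, and none of the 14 passed with an estimated correlation, for which adjusted p among them ran from 0.107 (interferon-stimulated genes) to 0.42 (acute phase proteins). fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, called 13 lists, 12 of them among the 14. It gave adjusted p = 0.000762 for the STAT3 and interferon lists, and the list it called that camera did not was that of TGF-beta responsive genes (0.0243). The lists of cholesterol synthesis (0.122) and acute phase genes (0.316), called by camera, did not pass with fry. For some lists the count of single genes past the threshold was near that of random lists matched on level. Those held on average 1.32 for TGF-beta responsive genes, 1.12 for the unfolded protein response, 0.94 for cholesterol synthesis and 0.73 for class I antigen presentation, against 1 in each list. For the STAT3 list they held 1.32, against 10 higher and 1 lower.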

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

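Tests of array weights after cyclic loess, of silent genes and of a deviation shared with a control array were chosen only after the results they bear on had been seen, and so was the use of a resampled spread for the cell type test. Probe sets outside the comparison also changed. With all 33297 probe sets in the fit, 13 of the 12083 without a named gene were higher and 10 lower after oncostatin M, and of 1754 with several genes 4 were higher and 10 lower. These were shares of 0.19% and 0.8%, against 3.42% of the genes in the main fit, which held fewer tests. Probe sets 7979505 and 8166632 had the largest rises among those without a gene (1.64, SE 0.07, and 1.41, SE 0.07), and 7943413 and 8058273 the largest falls (-0.97, SE 0.08, and -0.92, SE 0.16). The means of 7943413 (5.865 in control and 4.895 after oncostatin M) lay within the range of silent genes, so the size of its fall is uncertain. Groups of 3 arrays were not tested for outliers.

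Chance was weighed for the 630 genes called. In 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, as many genes passed the threshold, and the highest count in any other split was 0. With 10 splits, no share under 0.05 can be reached.

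Oncostatin M 1 differed from oncostatin M 2 and 3 more than any other array differed from its group: its weight was 0.226, and the median deviation of 10 equal bins of genes, ordered by level, from the other 2 arrays ran from 0.20 at low to middle levels to -0.12 at high levels. The first principal component (46.9% of the variance) placed it at 26.71, oncostatin M 2 and 3 at 3.72 and 3.62, and the controls between -17.76 and -5.78. Oncostatin M 2 and 3 correlated more closely with a control (up to 0.9941 and 0.9951) than with oncostatin M 1 (0.9922 and 0.9931). An intensity-dependent scaling of that array as the whole cause is argued against by cyclic loess, after which its weight was 0.306 and still the lowest of the 6 in each of 50 resamplings of the genes. A response to oncostatin M peculiar to that sample predicted that no untreated array would share its deviation. Control 2, untreated, shared it (r = 0.549 across 16272 genes with unadjusted limma p of at least 0.05), against 0.047 for control 1 and -0.607 for control 3. Deviations offset each other within the group, and genes are not independent replicates. At a mean level of 5.03 both oncostatin M 1 and control 2 lay above their groups (0.147 and 0.069). At 11.02 both lay below (-0.087 and -0.026). A common trend with level may thus give the correlation, which was not computed after cyclic loess. Genes with lower p were left out, so a peculiar response among responding genes stays open. Raised background may contribute, since the median deviation of 409 olfactory receptor and keratin-associated protein genes on oncostatin M 1 was 0.155, above the 0.099 of random lists matched on level. RNA of another cell type stays open: medians of epithelial, endothelial and leukocyte markers lay at percentiles of 95.9, 96.4 and 71 among matched random lists, each under the bound set for it by less than the spread of its members. By the rule written before this test, medians under their bounds counted against this explanation. The spread was brought in after the values were seen.

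All 17 cholesterol genes lay lower after oncostatin M, and a response to the treatment and joint variation between samples, apart from the treatment, cannot be told apart here. The list's mean level was 9.22 ± 0.10 in controls and 8.97 ± 0.14 after oncostatin M. It was lowest on oncostatin M 1 (8.816, against 9.001 and 9.094 in its group), the array that differed most from its group. The lowest control lay 0.054 above the highest oncostatin M array, less than the widest range within a group, 0.278, so 3 arrays against 3 leave both open.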

How the results depend on the processing

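All alternatives except cyclic loess, leaving out both oncostatin M 1 and control 2, and the silent-gene covariate, which were chosen after seeing the data, were set before the data were examined. All 630 genes called kept their sign in every alternative that held them. Counts of genes higher and lower (316 and 314; by at least 2-fold 70 and 34) moved by over 1.5 times as follows. Over all probe sets 176 were lower, with more tests. Array weights gave 667 and 610, and 21 lower by at least 2-fold. An adjusted p of 0.01 gave 175 and 112, a test against a 1.2-fold change 130 and 67, and a minimum change of 1.5-fold in place of 2-fold 187 and 137, by their construction. The silent-gene covariate gave 603 and 675, of which 630 were the genes called before. For the covariate, the weights and leaving out 1 array the cause was not tested, and neither of the first 2 is taken as the better fit. Leaving out 1 array gave 156 (without control 1) to 400 (without oncostatin M 1) higher and 105 (without control 1) to 332 (without oncostatin M 1) lower, and by at least 2-fold 63 to 79 higher and 20 (without oncostatin M 1) to 41 lower. Leaving out both oncostatin M 1 and control 2 gave 324 and 261. With a replicate block the counts were 255 and 223 (by at least 2-fold 70 and 37). Deviations of same-numbered arrays from their group means correlated across genes at 0.064, -0.456 and 0.511, so the numbers were not taken to pair the samples. By these deviations 3 of the 6 arrays correlated best with their own number. With 3 arrays per group, deviations offset each other within the group, which limits this check. Of 113 named genes, the replicate block ended the call of 22, leaving out 1 array that of 1 (oncostatin M 1) to 46 (control 1), the adjusted p of 0.01 that of 43 and the test against 1.2-fold that of 53. Signs reversed in 27 cases of 11 results, none past the threshold in either fit; for lists the sign is that of the test, and the median is printed. LIFR was 0.035 with array weights, 0.021 without oncostatin M 1 (-0.146 to 0.021 without 1 array) and 0.028 without both arrays, and COL1A1 0.015 without oncostatin M 3. Collagens gave -0.018, -0.014 and 0.014 without control 1, control 2 and oncostatin M 3 (lowest -0.100). Other matrix gave -0.087 (median centring), -0.072 (both filters on dim genes), -0.057 (cyclic loess), -0.026 and 0.001 (without control 1, oncostatin M 3; lowest -0.113). The interleukin-6 family gave 0.004 with both filters and -0.017 with fry, and growth factors 0.044 with fry. Epithelial markers gave -0.079 and -0.081, and endothelial -0.025 and -0.041, with array weights and without oncostatin M 1; endothelial also 0.007 without control 3 and -0.028 without both arrays (highest without 1 array 0.101 and 0.096). Heat shock gave -0.031 without oncostatin M 1 (lowest -0.094), cell cycle -0.017 and -0.003 without oncostatin M 2 and 3 (highest 0.079), and ribosomal proteins 0.008 without oncostatin M 2 (highest 0.016). With array weights the collagens list was called lower (-0.117, adjusted p = 0.0041; range over its alternatives 0.0041 to 0.922), the cell cycle list higher (0.09, 0.00261; range 0.000414 to 0.923), and the acute phase and prostaglandin lists lost their calls (0.337 and 0.0859). For other changed list calls the cause was not tested. The acute phase list lost its call with both filters on dim genes (0.0895 and 0.0758), quantile normalization (0.0633), the probe set of largest spread (0.0647), fry (0.316), cyclic loess (0.128), the covariate (0.0716) and without both arrays (0.268), the cholesterol list with fry (0.122), and the prostaglandin list without both arrays (0.0675). The cell cycle list was called higher without both arrays (0.00169) and with the covariate (0.0229), the unfolded protein list higher with cyclic loess (0.032) and the replicate block (0.0231), and the TGF-beta list lower with fry (0.0243). At 0.01, 3 lists lost their calls by construction. Signal over background limits genes of low level, where RMA shrinks changes: 7 of 105 named genes that passed lay among silent genes in both groups and 15 in 1.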

Other observations

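The genes and lists in this part were chosen after the results had been seen, and so was the adjustment over the 2 lists; the predictions for the lists of NRF2 and NF-kappaB targets were written before those lists were tested, when several NF-kappaB members had been seen uncalled. Families of genes whose symbols share a start are named here where at least 3 members passed and all of these moved alike. Of 19 semaphorins, which guide axons and cells, 6 fell and none rose. Besides SEMA3D and SEMA7A these were SEMA6A (-0.78, SE 0.09), SEMA6D (-0.62, SE 0.08), SEMA3C (-0.56, SE 0.09) and SEMA3A (-0.40, SE 0.07). Of 12 genes of the BMP family 3 rose, BMP4, BMP2 (0.89, SE 0.14) and BMP5 (both means below that of silent genes), and of 11 ABCC transporters 3 rose, ABCC4 (0.53), ABCC1 (0.49) and ABCC5 (0.47). In the TMEM family, named for transmembrane proteins and not for a shared function, 3 of 214 fell (TMEM35A -0.57, TMEM200A -0.48, and TMEM108 within the range of silent genes). Of 229 families tested with camera none passed, with adjusted p = 0.102 for ABCC, 0.324 for BMP, 0.357 for semaphorins and 0.995 for TMEM, and none of these 4 passed with fry (adjusted p = 0.386, 0.548, 0.22 and 0.999). The lowest camera p was that of 11 integrin alpha genes (ITGA, median -0.172, adjusted p = 0.102), of which none passed singly, and theirs was the family that passed with fry (adjusted p = 0.0266). Leaving out 1 array ended calls for SEMA3A and TMEM108 in 5 of 6 fits, ABCC5 in 4, ABCC1 and TMEM35A in 3, SEMA3C, BMP2, BMP5 and TMEM200A in 2 and ABCC4 in 1 (highest adjusted p 0.19, ABCC5 without control 1).

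SLC7A11, AKR1C1 and NMRAL2P (1.61, SE 0.18) rose, and a hypothesis was that targets of NRF2, the regulator of antioxidant genes, rise as a group. Of 17 other targets 16 lay above 0, with a median of 0.309, and GCLC (0.66, SE 0.07), HMOX1 (0.87, SE 0.12) and EPHX1 (0.38, SE 0.08) passed the threshold. camera gave p = 2.88e-11 at the preset correlation and p = 0.0649 with an estimated correlation, and without single arrays the latter ran from 0.0534 to 0.152; adjusted over the 2 lists it was 0.0649. fry, which asks whether the list moved in a common direction and not whether it moved more than other genes, gave an adjusted p of 0.0126. The members moved upward on balance, but they also vary together (estimated correlation 0.441), and whether they rose more than other genes stays open.

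TNFAIP3, NFKBIA (-0.57, SE 0.08) and IL6 fell, and a hypothesis was that targets of NF-kappaB fall as a group. Of 21 other targets 5 lay above 0, with a median of -0.129. BIRC2 (-0.42) and TNIP1 (-0.39) fell, and SOD2 rose by 0.66. camera gave p = 0.0105 at the preset correlation and p = 0.0487 with an estimated correlation, the latter meeting the bound set for it, but adjusted over the 2 lists tested it was 0.0649, and without single arrays it ran from 0.0559 to 0.103. fry gave an adjusted p of 0.00329 for movement in a common direction. The members moved downward on balance, and whether they fell more than other genes is not settled by these arrays. EPHX1, BIRC2 and TNIP1 each lost their calls in 5 of 6 fits that left out 1 array.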
